A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

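Poly(A) RNA of budding yeast (Saccharomyces cerevisiae) was sequenced from a wild-type strain (WT) and from a strain labelled T4V, with 2 libraries per genotype. T4V stands for the replacement of threonine by valine at position 4 of the heptad repeats in the C-terminal domain (CTD) of the largest RNA polymerase II subunit, the product of RPO21. Per the labels' protocols, RNA was extracted with phenol and chloroform, selected on oligo-dT beads in repeated rounds, fragmented, ligated to adapters at both ends so that the strand was kept, amplified by PCR and sequenced on an Illumina Genome Analyzer IIx. The medium, the growth phase and the strain background were not given in the sources used here.

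Per the submitters' processing notes, reads were placed with Bowtie2 on the sacCer3 assembly. The Bowtie2 version, the counting program, the gene annotation and the strand setting were not given in the sources used here. The authors deposited their values as RPKM, read counts scaled by gene length and library size, in 1 table of 7126 genes with a column for each of the 4 libraries. The column names gave the genotype but did not tie a column to a replicate number, so the columns are called WT library A and B and T4V library A and B. No library was pooled with another.

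The low RPKM values were whole multiples of the value of 1 read, which depends on the exonic length of the gene and the size of the library. Reads per gene were therefore recovered from RPKM, exonic length and library size. Of the low genes, 99.3% to 99.6% came out within 0.1 of a whole number of reads, and among genes with an intron all did so with the exonic length. The recovered totals behind the RPKM scale were 4068000 reads in WT library A, 3655000 in WT library B, 3355000 in T4V library A and 4261000 in T4V library B. A single read in a gene of 1 kb was worth 0.246, 0.274, 0.298 and 0.235 RPKM in these libraries. The limit that a count of 0 allows was set at 3 reads, or 0.738, 0.821, 0.894 and 0.704 RPKM for a gene of 1 kb. Reads amplified by PCR without molecular identifiers are not independent molecules, so these limits and the read-count intervals cover counting error only.

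Genes were joined to the RefSeq annotation of the R64 assembly, the release that sacCer3 is made from. Of the 7126 genes, 6048 matched by systematic name and 114 RNA genes by symbol, and 964 did not match and have no coordinates here. In 12 of 12 gene pairs where 1 gene lay within the antisense strand of an abundant partner, the smaller gene's mean RPKM was under 10% of the partner's. Counting by strand would give this, but so could dropping reads that fall on overlapping genes, so the strand setting stays open.

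The test was limma on log2(RPKM + 1), with moderated variances that follow a trend with abundance, 2-sided, on the deposited values without further scaling. Genes with an RPKM of at least 1 in at least 2 libraries were tested. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(RPKM + 1) scale and T4V minus WT, which understates the change of low genes. Where the wild-type libraries held few reads, the ratio of reads between genotypes, corrected for library size, is given with an exact binomial 95% interval. Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01, for lists with at least 5 measured genes, adjusted over the 43 lists tested. An alternative estimated the correlation from the data. That form rests on 2 residual degrees of freedom, so it could hardly call any list. Of 44 lists, 41 were written down by gene name and 3 were defined from the annotation, all before the data were examined. R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, were used.

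The rule for the genes named was fixed before the data were examined. It took RPO21 and HTZ1, the 12 largest rises and the 12 largest falls among called genes with a standard symbol and a mean RPKM of at least 10, up to 4 called genes per list with the largest change, and any gene of the phosphate and galactose lists. Genes outside the rule are said to have been chosen after their values were seen.

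The fit was tested on simulated tables with 200 changed genes among 5641, with 2 libraries per group. Over 20 tables, it recovered 55.8% of genes changed 1.5-fold, 87.6% of genes changed 2-fold and 96.6% of genes changed 4-fold, and 6.05% of its calls were false. Simulated genes varied independently, with a log2 SD of 0.097 between replicates taken from the WT libraries. Differences that many genes of a library share were left out, so the false share in the real data may be higher. Alternatives set before the data were examined changed the pseudocount, the filter on low values, the scaling, the variance model, the threshold and the list test, and left out each library in turn. Voom on the recovered reads and a fit without small nucleolar and nuclear RNA genes were added after the data were seen.

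Replicates differed by more than sampling noise, with a chi-square per gene of 2.97 between the WT libraries and 2.35 between the T4V libraries, against 14.2 to 17.3 between genotypes. The labels do not say that the replicates came from separate cultures, so the p-values of single genes measure the spread between these libraries, which may be technical. Camera p-values at the preset correlation set the genes of a list against other genes. They treat genes rather than libraries as the units, so they do not measure the spread between libraries or cultures. With 2 libraries per group, an exact permutation test of a single gene cannot give a 2-sided p under 0.333. Of the fixed names, CRT1 was not matched to a gene of the table without ambiguity and was left out.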

Results

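RNA of 2 wild-type and 2 T4V budding yeast libraries was compared, with RPKM values for 7126 genes. The series asks how threonine 4 of the RNA polymerase II CTD bears on transcription and on chromatin remodelling that involves the histone variant Htz1. The libraries held 4068000 and 3655000 reads for wild type and 3355000 and 4261000 for T4V, as recovered from the RPKM steps. Between 6067 and 6178 genes had a value above 0 in each library, and 703 genes were at 0 in all of them. The 10 most abundant genes took 12.3% and 12.2% of the reads in the WT libraries and 11.3% in each T4V library.

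RPO21 (YDL140C), the gene of the altered subunit, lies on chromosome IV at 205360 to 210561 on the minus strand of the R64 assembly. It had 52.5 ± 1.26 RPKM in wild type and 52.4 ± 2.36 in T4V (SD, n = 2 each). HTZ1 (YOL012C), on chromosome XV at 303579 to 303983, had 102.0 ± 8.56 RPKM in wild type and 96.8 ± 6.66 in T4V (SD, n = 2 each). Neither gene passed the test, with limma adjusted p of 0.987 for RPO21 and 0.636 for HTZ1. Their 95% intervals of log2 fold change ran from -0.22 to 0.22 and from -0.30 to 0.15. RPKM per gene does not show the base change, so the genotype of a library rests on its label alone, and each direction given here is that of the libraries labelled T4V.

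The phosphate-response genes were much higher in the libraries labelled T4V. Of the 17 genes of the PHO regulon, which yeast cells use to take up and store phosphate, 15 rose, and 16 did when adjusted over the list alone. PHO84, the high-affinity phosphate transporter, went from 0.356 ± 0.284 to 541 ± 21.4 RPKM (SD, n = 2 each). PHO5, a secreted acid phosphatase, went from 15.4 ± 1.70 to 224 ± 10.8 RPKM. The vacuolar transporter chaperone genes VTC1, VTC2, VTC3 and VTC4, which make polyphosphate, rose by log2 fold changes of 1.35, 0.81, 2.13 and 1.70.

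PHO84 (YML123C) lies on chromosome XIII at 24037 to 25800. It had 5 reads over both WT libraries and 7250 over both T4V libraries, a ratio of 1470 with an interval of 629.8 to 4530. PHO89, a sodium-coupled phosphate transporter on chromosome II at 796798 to 798522, had 9 and 829 reads, a ratio of 93.4 with an interval of 49.0 to 205. SPL2, a regulator of low-affinity phosphate transport on chromosome VIII at 374654 to 375100, had 1 read in wild type and 155 in T4V, a ratio of 157 with an interval of 27.8 to 6248. PHM6 had 1 and 22 reads, a ratio of 22.3 with an interval of 3.61 to 920.7. PHO5 lies on chromosome II at 429548 to 430951 and rose by 3.78 ± 0.11 (SE) with an adjusted p of 2.0e-05.

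The glycerophosphoinositol transporter gene GIT1 rose by 2.51, and the kinase inhibitor gene PHO81 and the vacuolar phosphatase gene PHO8 by 1.28 and 1.15. PHM8 rose by 1.08. The acid phosphatase genes PHO11 and PHO12 rose by 2.81 and 2.76, but they are near-identical copies and relatives of PHO5, so the split of reads among them is uncertain. PHO86 had a log2 fold change of 0.29 (limma adjusted p = 0.0591) and HOR2, also called GPP2, one of 0.02 (adjusted p = 0.894). The median over the 17 genes was 2.13, with a camera adjusted p of 1.7e-15 at the preset correlation and an adjusted p of 0.296 with an estimated correlation. Without T4V library A or B, only 5 or 7 of the 17 genes were called, while 15 were called without either WT library.

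**Figure D1:**
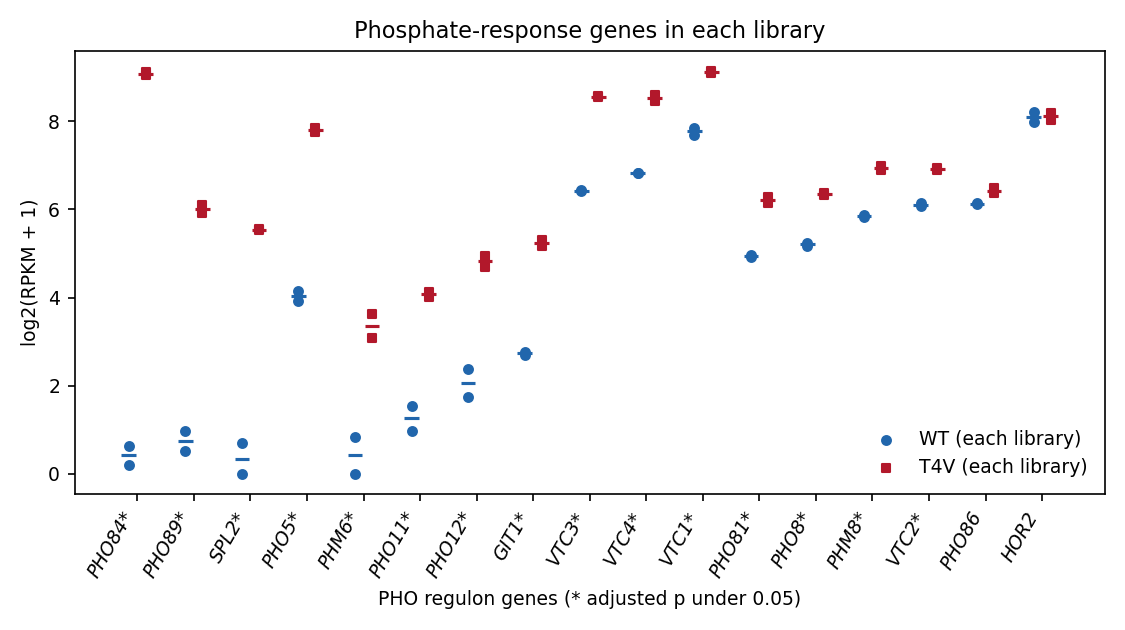
Level of each of the 17 PHO regulon genes as log2(RPKM + 1) in the 2 WT libraries (circles) and the 2 T4V libraries (squares), with short lines at the group means and a star for an adjusted p under 0.05. For the 15 starred genes both T4V libraries lie above both WT libraries, from PHO84 with a log2 fold change of 8.66 to VTC2 with 0.81.

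Among the regulators and low-affinity transporters of the same pathway, 2 genes were called. PHO80, the cyclin of the pathway's kinase, rose by 0.50, and PHO2, a transcription factor that acts on PHO5, rose by 0.43. Both calls were lost under each other scaling, without a filter on low values and without any 1 library. The other 5 of the 7 genes on this list did not pass the test, and 2 rose and 2 fell adjusted over the list alone, while voom called 4. The list had a median of -0.04 and a camera adjusted p of 0.785.

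Across the genome, 1063 of 5935 genes tested were called, 692 higher and 371 lower in T4V. Of these, 131 were higher and 59 lower by at least 2-fold. In all 1063 called genes, both T4V libraries lay on the same side of both WT libraries. The calling rule largely fixes this outcome with 2 libraries per group, so it is no separate evidence. Groups did not overlap for 3679 genes, or 62% of those tested, where chance gives 33.3% on average. All genes share the same 4 libraries and are not independent, so a library-wide difference of any cause could raise this share. Higher genes made up 65.1% of the calls, but 53.3% after median-of-ratios scaling (536 higher, 470 lower), 50.3% after quantile normalization (449 and 443) and 52.8% after rescaling without ribosomal protein and the 20 most abundant genes (528 and 472). The count fell to 10 higher and 6 lower without T4V library A, and to 17 and 10 without T4V library B.

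Outside the phosphate list, the largest rises included SNZ1, a vitamin B6 synthesis gene on chromosome XIII at 458408 to 459301. It went from 31.8 ± 2.51 to 155 ± 14.0 RPKM (SD, n = 2 each), a log2 fold change of 2.25 with a limma adjusted p of 0.000126. UPS3, a mitochondrial protein gene, rose by 1.92. The small nucleolar RNAs SNR62 and SNR60 rose by 2.29 and 2.22, from 31 and 6 reads in wild type to 150 and 29 in T4V. SNR71 had 2 and 14 reads, a ratio of 7.10 with an interval of 1.63 to 64.3. Its call was lost under each other scaling, with a pseudocount of 0.1, without a filter on low values, without the trend or with the robust variance model, and its log2 fold change was 1.69 without WT library B against 3.03. SNR60 overlaps another gene on the same strand, so its reads are uncertain.

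Steep falls included single genes and an overlapping pair. LOT5, on chromosome XI at 98721 to 99641, went from 47.0 ± 1.41 to 6.99 ± 1.65 RPKM (SD, n = 2 each), a log2 fold change of -2.60 with a limma adjusted p of 0.000491. GCD10, a subunit of a tRNA methyltransferase, had a log2 fold change of -2.13, from 93.9 to 20.7 RPKM. PTC2, a protein phosphatase gene on chromosome V at 335946 to 337340, went from 365 ± 48.4 to 82.2 ± 2.24 RPKM, a log2 fold change of -2.13. AIM4 had a log2 fold change of -2.09 and MOD5, a tRNA modification enzyme gene, one of -1.85. SEC39, YPS3, BNA7 and MRF1 fell by 1.53, 1.49, 1.45 and 1.42. HMS2 fell by 1.91 and YJR146W, which overlaps it on the same strand and was named after its values were seen, by 2.28, so their reads may be shared. The small nucleolar RNAs SNR86 and SNR76 fell by 2.22 and 1.86.

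ADH1, the main alcohol dehydrogenase of fermenting cells on chromosome XV at 159548 to 160594, fell by 1.35, from 2210 ± 15.6 to 865 ± 29.1 RPKM (SD, n = 2 each). It was the steepest fall on the list of glycolysis and ethanol formation, of whose 17 genes 4 were called, and 2 rose and 4 fell adjusted over the list alone, while voom called 8. TDH1 and ENO1 rose by 1.16 and 0.62, and ENO2 fell by 0.27, although ENO2 stood at 0.12 after quantile normalization. TDH1 has close relatives TDH2 and TDH3, and ENO1 and ENO2 are close relatives of each other, so their reads may be shared. The list had a median of -0.09 and a camera adjusted p of 0.0813, which passed at 0.0316 after median-of-ratios scaling and after the rescaled total (0.0316 to 0.771 over the alternatives). Its median was 0 after quantile normalization.

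**Figure D2:**
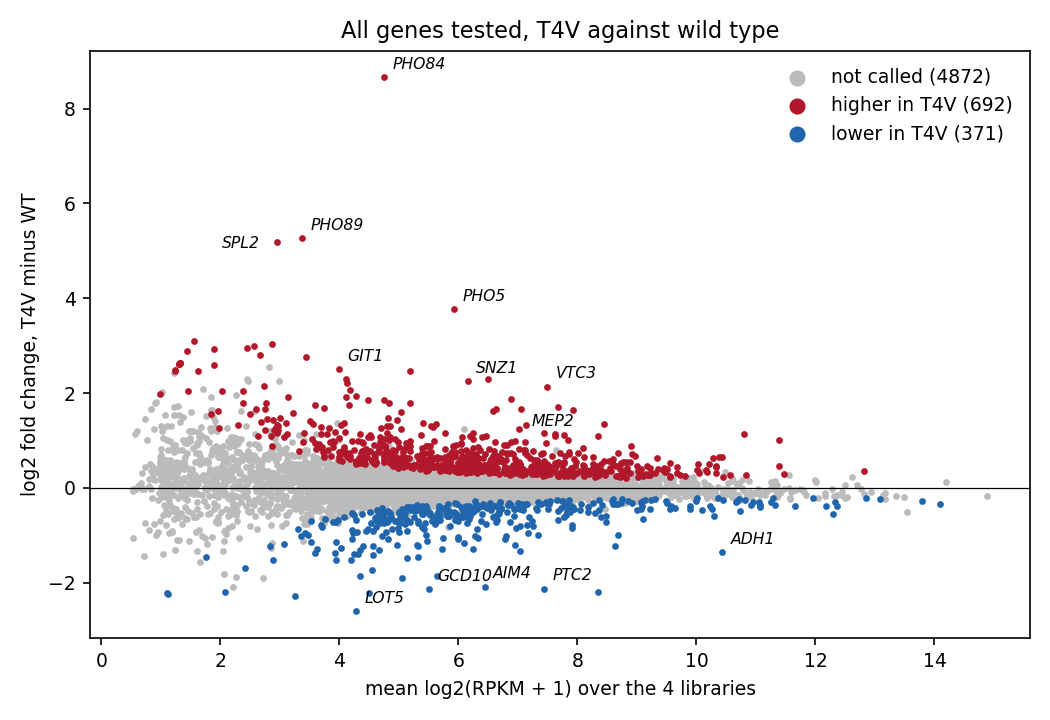
Log2 fold change, T4V minus WT, against the mean log2(RPKM + 1) over the 4 libraries for the 5935 genes tested. The 692 genes called higher and the 371 called lower are coloured, and phosphate-response genes PHO84, PHO89, SPL2 and PHO5 stand above the rest.

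Many genes of stress and nutrient limitation were called higher. Of 40 general stress genes 26 rose, and 30 when adjusted over the list alone, with a median of 0.56. DDR2, MOH1, SPI1 and GAC1 rose by 1.63, 1.23, 1.15 and 1.14. Of 21 genes under nitrogen catabolite repression, which are held down while good nitrogen sources last, 13 rose, and 16 adjusted over the list alone, with a median of 0.67. The ammonium permease gene MEP2 went from 73.8 ± 1.98 to 236 ± 18 RPKM (SD, n = 2 each), and DAL80 and PUT1 rose by 1.85 and 1.31. Of 15 stationary phase genes 6 rose, and 7 adjusted over the list alone, among them SNZ1, SNO1 and PIR3. Camera adjusted p were 2.2e-10, 1.7e-07 and 0.00494 for the stress, nitrogen and stationary phase lists, and the adjusted p with an estimated correlation were 0.315, 0.296 and 0.315. Without T4V library A, or without T4V library B, at most 1 gene of each of these lists was called, and the stress genes called were 17 without WT library B and 12 without the variance trend.

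Genes of several metabolic lists were also called. Of 52 amino acid biosynthesis genes, 20 rose and 1 fell, and 34 rose and 3 fell adjusted over the list alone. HIS4, HIS5, LYS1 and ARG7 rose by 1.10, 1.01, 1.10 and 0.74. Of 34 genes of the respiratory chain and ATP synthase 10 rose, and 16 adjusted over the list alone, with COX7, COX12 and COX6 at 0.67, 0.51 and 0.45. Of 15 TCA cycle genes 4 rose, namely LSC2, CIT1, SDH2 and MDH1, and 10 did adjusted over the list alone. Of 20 iron regulon genes 8 rose, and 9 rose and 1 fell adjusted over the list alone. The iron oxidase gene FET3 rose by 1.26, the siderophore transporter gene SIT1 by 1.13 and the copper chaperone gene ATX1 by 0.90. Of 32 proteasome genes 10 rose and 1 fell, and 12 rose and 1 fell adjusted over the list alone, with RPN4 at 0.47 and RPN10 at -0.44. MDH1 lost its call under each other scaling, SIT1 after quantile normalization, without the trend and without WT library B (log2 fold change 0.72), and RPN4 without WT library A or B.

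The camera adjusted p of these lists were 1.9e-05 for amino acids, 4.1e-05 for respiration, 0.00112 for the TCA cycle, 0.00494 for iron and 0.00494 for the proteasome. With an estimated correlation, the adjusted p were 0.296, 0.296, 0.522, 0.315 and 0.423 in that order. After median-of-ratios scaling 14 amino acid and 5 proteasome genes rose, after quantile normalization 13 amino acid, 6 respiratory, 5 iron and 3 proteasome genes, and after the rescaled total 13 amino acid and 4 proteasome genes. Without the variance trend, 4 amino acid, 1 respiratory, 2 TCA cycle, 4 iron and 0 proteasome genes rose by limma, where 15 proteasome genes were higher at an unadjusted p under 0.05 with the trend. Voom called 32, 16, 9, 10 and 14 higher in the same order. Without T4V library A, or without T4V library B, at most 1 gene of each of these lists was called. Without WT library A 11 amino acid, 6 respiratory and 3 proteasome genes rose, and without WT library B 12 amino acid, 5 iron and 2 proteasome genes.

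Growth-related lists held genes that were called lower. Of 137 cytosolic ribosomal protein genes 17 fell, and 15 adjusted over the list alone, with a median of -0.12. RPL21B and RPL24B fell by 0.55 and 0.50, although most such genes have a near-identical copy and the split of reads between copies is uncertain. RPL21B lost its call after quantile normalization, at -0.38 with an adjusted p of 0.103. Of 62 ribosome biogenesis genes 7 fell, and 7 adjusted over the list alone, with SDA1, UTP8 and HAS1 at -0.99, -0.50 and -0.47. Of 17 genes of inositol and phospholipid synthesis 5 fell, and 8 adjusted over the list alone. INO1, the inositol synthesis enzyme, fell by 0.76, and PIS1 and CHO1 each fell by 0.41. Of 17 G1 and S phase genes 4 fell, and 4 adjusted over the list alone, namely MCD1, CLN2, PCL1 and SVS1. The camera adjusted p were 6.1e-12, 1.8e-07, 4.1e-05 and 0.00264, and the adjusted p with an estimated correlation were 0.296, 0.296, 0.296 and 0.522 in the same order. The ribosomal protein genes that fell were 35 after median-of-ratios scaling and after the rescaled total, 13 after quantile normalization and 43 with voom, and 10 without WT library A. The ribosome biogenesis genes that fell were 11 after median-of-ratios scaling, 13 with voom and 3 without WT library B, and the inositol genes 8 and 9 in the first pair of these. Without the variance trend limma called 0 ribosomal protein and 0 G1 genes, of which 51 and 5 were lower at an unadjusted p under 0.05 with the trend, and 1 gene of each other list. Without WT library A 2 G1 genes fell, and 1 without WT library B. Without T4V library A, or without T4V library B, at most 1 gene of each of these lists was called.

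The chromatin and transcription lists tied to the question of the series held few called genes. Of the 11 genes listed for the SWR1 complex, which places Htz1, and HTZ1 itself, YAF9 alone was called, at -0.27 (camera adjusted p = 0.684). That list did not hold every subunit of the complex, as ARP4, RVB1 and RVB2 were placed on the INO80 list alone. Of 14 INO80 complex genes ARP4 fell by 0.34 (camera adjusted p = 0.329). No gene was called by limma among 9 histone genes, where 2 were lower at an unadjusted p under 0.05 and voom called 0. The histone list had a median of -0.12 and a camera adjusted p of 0.0651, which passed at 0.0261 after median-of-ratios scaling, 0.0265 after the rescaled total, 0.0364 with camera on ranks, 0.0320 without WT library A and 0.0345 without T4V library B (0.0261 to 0.522 over the alternatives). Several histone genes are near-identical pairs, so their reads may be shared. Among 12 RNA polymerase II subunit genes limma called 0, 3 had an unadjusted p under 0.05 and voom called 2 (camera adjusted p = 0.537). With limma RPB8 and RPB5 were called lower under each other scaling, at -0.31 and -0.32 after median-of-ratios scaling, and RPB8 also with an RPKM of at least 10 required. Of 16 CTD kinase and phosphatase genes SGV1, the catalytic subunit of the Bur kinase, fell by 0.80 and SSU72, a CTD phosphatase, by 0.47 (camera adjusted p = 0.241). Among 18 elongation and export genes only HPR1 was called, at 0.44, and it lost the call under each other scaling and without any 1 library. RPC11 rose by 0.67 among 19 subunit genes of RNA polymerases I and III, and both lists had a camera adjusted p of 0.482. Adjusted over the list alone, limma called 0 genes of the SWR1, histone, RNA polymerase II and elongation lists, 1 lower of INO80, 2 lower of the CTD list and 1 higher of polymerases I and III. Voom called 2 INO80 genes, 3 of elongation and export and 3 of polymerases I and III. YAF9 and SSU72 lost their calls without WT library A or B, and ARP4 without WT library B.

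Of 8 galactose genes measured, 1 rose and 1 fell, and voom called 2 higher and 2 lower, adding GAL80 and PGM2. GAL4, the activator of the pathway, fell by 1.47, from 95 reads in wild type to 21 in T4V, and GCY1 rose by 0.65. The other 6 genes did not pass the test, and the same 2 were called adjusted over the list alone. Among the 6, GAL1, GAL7 and GAL10 stood at 6.54, 1.38 and 0.81 RPKM in wild type. In T4V they stood at 5.69, 2.09 and 1.23 RPKM. GAL7 and GAL10 were so low that the test says little about them. For GAL1 the 95% interval of log2 fold change ran from -0.73 to 0.38. Over the list, the median was 0.06, the mean was -0.14 and camera pointed to lower values, with an adjusted p of 0.576. GAL4 lost its call when any 1 library was left out, with adjusted p of 0.115 to 0.190.

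Carbon source genes were mixed. Of 21 glucose-repressed genes 4 rose and 1 fell, with IDP2, CTA1, HXK1 and MAL31 at 1.47, 0.83, 0.82 and 0.66 (camera adjusted p = 0.241, and 0.0368 with an RPKM of at least 10 required, out of 0.0368 to 0.522 over the alternatives). Of 7 hexose transporter genes, HXT1 fell by 0.81 and HXT2 rose by 0.71 (camera adjusted p = 0.473). Of 24 sulfur and methionine genes 9 rose and 2 fell, with MET10 at 0.69 and SAM3 at -0.77 (camera adjusted p = 0.482). Of 10 zinc genes 3 rose and 1 fell, with ADH4 at 1.13 (camera adjusted p = 0.647). Among 23 ergosterol genes ERG24 fell by 0.49 (camera adjusted p = 0.576). Of 23 heat shock and chaperone genes 3 rose and 4 fell, with AHA1 at -0.73 and HSP78 at 0.53 (camera adjusted p = 0.0514, passing at 0.0261 after median-of-ratios scaling, 0.0265 after the rescaled total, 0.0455 without a filter on low values, 0.0489 without WT library B and 0.0488 without T4V library B, with 0.0261 to 0.505 over the alternatives). Of 29 cell wall genes 7 rose and 4 fell, with GSC2 at 1.29 and TIP1 at -1.08 (camera adjusted p = 0.504). Adjusted over the list alone, 5 rose and 1 fell of the glucose-repressed genes, 2 and 1 of the hexose transporters, 9 and 3 of the sulfur genes, 3 and 2 of the zinc genes, 0 and 1 of the ergosterol genes, 3 and 4 of the heat shock genes and 12 and 4 of the cell wall genes. Voom called 10 glucose-repressed, 5 hexose transporter, 4 ergosterol and 18 cell wall genes.

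Of the mating-type lists, 3 of 7 a-specific genes rose, and 3 adjusted over the list alone. The a-factor gene MFA1 rose by 1.67, AGA2 by 0.63 and BAR1 by 0.40 (camera adjusted p = 0.0179, adjusted p = 0.347 with an estimated correlation). Of 4 alpha-specific genes measured, limma called 0, 0 had an unadjusted p under 0.05 and voom called 1. STE18 and RME1 rose by 0.55 and 0.35 among 11 haploid-specific genes, and AGA1 and PRM5 by 0.67 and 0.33 among 13 pheromone-response genes (camera adjusted p of 0.329 and 0.532). Among 20 sporulation genes limma called 0, 4 had an unadjusted p under 0.05 and voom called 5 (camera adjusted p = 0.576). MCM6 fell by 0.33 among 24 genes of mitosis and early G1 (camera adjusted p = 0.406), and UBI4 and DIN7 rose by 0.85 and 0.67 among 14 DNA damage genes (camera adjusted p = 0.513). Of 10 genes used as strain markers 3 rose, namely ADE2, CAN1 and LYS2 (camera adjusted p = 0.164). Adjusted over the list alone, 3 rose and 1 fell of the haploid-specific genes, 2 rose of the pheromone-response genes, and 2 of the DNA damage genes, and of the strain markers 6 rose and 2 fell. In the same way limma called 0 alpha-specific, 0 sporulation and 0 mitosis genes, where 10 mitosis genes had an unadjusted p under 0.05. Voom called 4 haploid-specific, 4 DNA damage, 7 mitosis and 7 strain marker genes. AGA1 and STE18 lost their calls under each other scaling and without a filter on low values, and PRM5 after quantile normalization and after the rescaled total. BAR1, RME1, DIN7 and LYS2 lost theirs after quantile normalization, and MCM6 without a filter on low values and without WT library A or B.

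Among multigene families, PAU12 was the 1 called of 8 PAU genes and COS6 the 1 called of 8 COS genes, and both families hold near-identical members whose reads are uncertain (camera adjusted p of 0.300 and 0.507). Of 80 small nucleolar and nuclear RNAs 13 rose and 7 fell (camera adjusted p = 0.513), and voom called 11. Of 253 genes with an annotated intron 21 rose and 20 fell, with a median of -0.03 and a camera adjusted p of 0.0685, which passed at 0.0261 after median-of-ratios scaling and 0.0265 after the rescaled total (0.0261 to 0.339 over the alternatives). Without ribosomal protein genes, 21 of 164 intron genes rose and 11 fell (camera adjusted p = 0.507). Of 132 genes within 20 kb of a chromosome end, 26 rose and 4 fell, with a camera adjusted p of 0.0842, which passed at 0.0261 after median-of-ratios scaling, 0.0265 after the rescaled total, 0.0438 with voom and 0.00367 with an RPKM of at least 10 required (0.00367 to 0.330 over the alternatives). Adjusted over the list alone, 3 PAU genes and 3 COS genes rose, 18 small RNAs rose and 8 fell, 20 intron genes rose and 19 fell, 21 and 11 without ribosomal protein genes, and 28 genes near chromosome ends rose and 4 fell. Voom called 2 PAU, 3 COS and 69 intron genes.

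**Figure D3:**
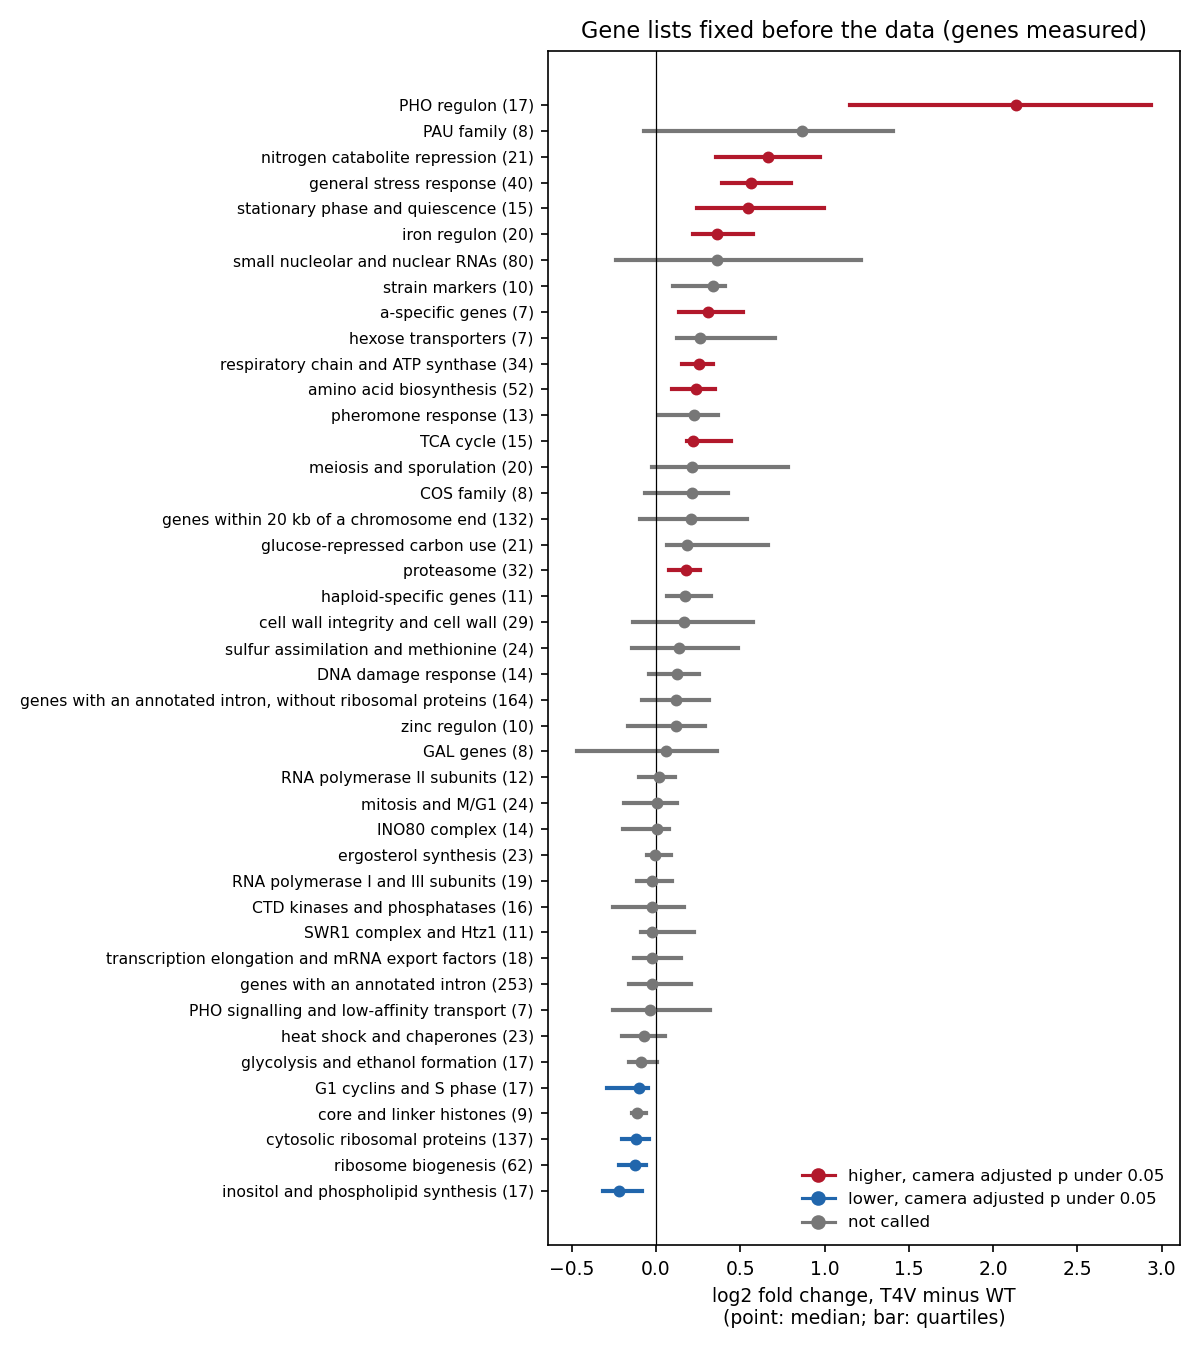
Median log2 fold change, T4V minus WT, of each gene list (points) with its lower and upper quartile (bars), for the 43 lists tested, with the number of genes measured in brackets. Lists with a camera adjusted p under 0.05 at the preset correlation are coloured, and the PHO regulon has the highest median, 2.13.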

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

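Voom on recovered reads and the fit without small nucleolar and nuclear RNAs were chosen after seeing the data. No paired analysis was possible because the columns carry letters but no replicate number (A minus B deviations correlated at -0.093 between groups over 4909 genes). No gene called with the design set beforehand was called in the opposite direction under any alternative. The numbers of higher and lower genes went from 692 and 371 to 265 and 134 without the variance trend and 449 and 443 with quantile normalization. They were 1010 and 585 with voom, and 326 and 165 with a 1.5-fold minimum. Leaving out 1 library gave 10 to 501 higher and 6 to 245 lower genes, with 483 and 228 without WT library A, 501 and 245 without WT library B, 10 and 6 without T4V library A, and 17 and 10 without T4V library B. Fewer libraries leave less to estimate the spread from, and the lone library of a group is then assumed to vary like the other group. Each of these fits held the same number of libraries, so that number does not explain why their counts differ. Without a T4V library the spread came from the WT pair alone, and without a WT library from the T4V pair alone. The cause of the difference was not tested. The PHO regulon kept a median of 1.32 to 2.15, and was no longer called with an estimated correlation (median 2.13, adjusted p = 0.296, against 4.36e-25 to 1.89e-08 in the other alternatives), and neither was any other called list. The a-specific list also lost its call without the variance trend (adjusted p = 0.0535, out of 0.00705 to 0.347). The galactose list was not called in any setting and had under 5 genes at an RPKM of at least 10. Camera has no robust option, so lists have no value for that variance model. Camera with an estimated correlation rests on 2 residual degrees of freedom and called no list, its smallest adjusted p being 0.296. It could hardly call any list, so a call lost there does not tell a robust list from a weak one. Of the 152 named genes called, 138 and 128 lost the call without T4V library A or B, 26 and 29 without WT library A or B, 58 without the trend, and 0 to 19 in each other setting. ENO2 turned to 0.12 with quantile normalization, and the glycolysis list to 0. Uncalled values near 0 changed sign, and the cause was not tested: HOR2 was at -0.029 (median-of-ratios), -0.037 (quantile) and -0.031 (rescaled total), and RPO21 at 0 with voom. Leaving out 1 library gave -0.088 to 0.135 for HOR2, -0.158 to 0.012 for HTZ1, -0.047 to 0.043 for RPO21, -0.048 to 0.081 for the RNA polymerase II list and -0.089 to 0.035 for the PHO signalling list. Depth limits genes of few reads, as 1 read in 1 kb is worth 0.235 to 0.298 RPKM.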

Other observations

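The gene groups in this paragraph and the next were put together after the values were seen, so their p-values are not independent evidence. Genes of purine and one-carbon synthesis were higher in the libraries labelled T4V. Of 16 such genes 13 rose, with a median log2 fold change of 0.59. ADE17, an enzyme of the last steps to IMP, went from 60.3 ± 2.64 to 224 ± 2.26 RPKM (SD, n = 2 each), a log2 fold change of 1.88. ADE1, MTD1, ADE12, ADE13 and ADE5,7 rose by 1.32, 1.24, 1.14, 0.97 and 0.97. The camera p was 1.3e-11 at the preset correlation and 0.0184 with an estimated correlation, neither adjusted.

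Genes of mRNA 3′ end formation and of termination by Nrd1 moved in both directions. Of 23 such genes 5 rose and 3 fell (camera p = 0.464, and 0.568 with an estimated correlation). NRD1, whose protein limits its own mRNA, rose by 1.02, and REF2, RNA14, PCF11 and RNA15 rose by 0.98, 0.71, 0.49 and 0.47. SYC1 and PTI1 fell by 0.92 and 0.62. IMD2, a GTP synthesis gene with upstream start sites, fell by 1.29, and URA8 rose by 0.72. YER088C-A, which was not matched to the annotation, went from 703 to 151 RPKM.

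Of the tests in the following paragraphs, those of scaling, glucose, exchanged labels, growth stage, deletion, neighbouring genes, carry-over and small RNA noise were chosen after the results were seen, and those of gene orientation and gene length before. Tests of glucose, neighbouring genes and small RNA noise replaced first forms whose values had been seen, which were a lower quartile of 0.068 over all 21 glucose-repressed genes, a median of -0.004 over adjacent genes outside the set of falls, and a ratio of 1.27 set against a bound fixed beforehand.

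The PHO regulon was higher in the libraries labelled T4V. Had a difference in scaling caused this, rescaling would remove the rise, but the median was 2.08 after median-of-ratios scaling. That scaling shifted fold changes by a median of only -0.0508, too little to remove a rise of this size. Lower glucose in those cultures could not be excluded: over the 10 glucose-repressed genes with a mean RPKM of at least 10, the quartiles were 0.136 and 0.779, and 4 rose and 1 fell. A difference in growth stage or nutrient supply between cultures may lie behind the rise, since the smallest median among the stress, stationary phase and nitrogen lists was 0.54, and it cannot be told apart from an effect of the genotype because no culture record was used here. Exchanged genotype labels could give the same values in the opposite sense, and RPO21, at -0.002, cannot settle it because the substitution need not change its level.

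Falls of at least 2-fold at 42 protein-coding genes with a mean RPKM of at least 10 were weighed as a set. Deletion of these genes would leave no reads, but the lowest had 7 over both T4V libraries, and a loss spanning neighbours would lower them, but 38 of the 42 had no gene lower by at least 2-fold beside them. For the other 4 a joint loss cannot be told apart from shared reads or shared regulation, with a median of -2.05 beside them: HMS2 and YJR146W overlap, and by systematic name PTC2 lies beside YER088C-A (-2.20) and KTR3 beside YBR206W (-1.17). Convergent orientation with the next gene was not more frequent among the 42 falls, at 38.1% against 53.5% of 4950 other genes (Fisher's exact p = 0.0612, odds ratio 0.535 with a 95% interval of 0.268 to 1.04), and an effect of the T4V genotype stays open as a hypothesis. Smaller falls beside these genes were not counted above. Of 79 adjacent genes outside the set, 7 were called lower by limma, and SGV1, beside ORC4, fell by 0.80.

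Small nucleolar and nuclear RNAs both rose and fell. More RNA without poly(A) tails in the T4V libraries would not lower abundant ones, but 6 of 37 fell, or 16.2%; for the rises it cannot be told apart from a genotype effect, as 25 of the 37 were positive, with a median of 0.371. Sampling noise alone would give genotypes no larger a difference than splits that mix them, but the median absolute difference of 0.622 was 2.14 times the larger of these, 0.259 and 0.291 (bootstrap 95% interval over genes 1.2 to 4.29). The first bound was wrong because noise alone makes a difference of 2-library means 0.71 of one between replicates, not 1.5. Variation between library preparations stays open, since 4 libraries give too few splits to exclude chance.

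Longer transcripts were not clearly lower in T4V, with Spearman's rho of -0.047 across 4996 protein-coding genes, which are not independent replicates (permutation p = 8e-04, Pearson's r = -0.06 with log2 length).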
